A study of Homo sapiens with 18 samples.

How the data were processed

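RNA sequencing libraries of NCI-H295R adrenocortical carcinoma cells were compared between 6 groups of 3 biological replicates, untreated or exposed for 48 h at a stated 20 nM to STA9090, PIK75, BGT226, STA9090 with PIK75 or STA9090 with BGT226. Per the labels, RNA was extracted with a column kit, its integrity was evaluated, and stranded total RNA libraries were made after depletion of ribosomal RNA and sequenced as paired ends. The integrity values, the counting strand, the annotation release, the dose of each agent within a combination and the vehicle are not given in the sources used here.

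The authors deposited 1 table of expected counts per gene, not normalized, with 58870 genes and 1 column for each of the 18 libraries. The submitters' processing notes name bcl2fastq 2.20, cutadapt 1.18, STAR 2.7.0f and RSEM 1.3.1 and the genome build hg38, without their settings. Of the gene IDs 99.54% are in GENCODE 29 when the version is ignored and 80.55% with it, and 98.05% of the symbols are equal to those of that release, which supplied positions and gene types. Because the release used for counting is not given, reads shared between overlapping, antisense or near-identical genes may be divided in ways that cannot be read from the table, and several such genes are said to be uncertain where they are named.

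Everything else was computed from that table with R 4.3.3. Counts were rounded to whole numbers, which changed a library total by at most 0.000381%. Genes were kept by the filterByExpr function of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 15787 genes, 82.4% of them protein-coding. Libraries were scaled by TMM, with factors from 0.9034 to 1.132. Library totals ran from 10.24 to 21.13 M counts. CPM are counts scaled to 1 M with those factors, and means are given with the SD of 3 libraries.

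The 18 libraries entered 1 model with a mean for each group and no covariate, so that all groups shared an estimate of the spread. The common dispersion was 0.01119, a biological coefficient of variation of 10.58%. Differences were tested with edgeR's quasi-likelihood F-test, and p was adjusted by the Benjamini-Hochberg method over all genes kept, with a threshold of 0.05. Log2 fold changes are fitted values with a prior count of 0.125, and their SE is the size of the log2 fold change divided by the square root of F. The 13 comparisons were the 5 treatments against untreated, each combination against each of its parts, the interaction of STA9090 with each PI3K inhibitor on the log2 scale, PIK75 against BGT226, and the combinations against each other.

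The 27 gene lists, 554 genes in all, covered heat shock chaperones, ER chaperones, ATF4 targets, FOXO targets, cholesterol synthesis, fatty acid synthesis, steroidogenesis, the IGF2 locus and WNT targets, G2/M and mitosis, G1/S and replication, the BCL2 family, hypoxia and glycolysis, ribosome biogenesis, lysosome and autophagy, ERK feedback, immediate early genes, NRF2 targets, NF-kappa-B, interferon, proteasome subunits, cytosolic ribosomal proteins, matrix and EMT, neuroendocrine markers, mitochondrial mRNAs, drug targets with the PI3K pathway, and markers of other cell types. The other list, 1 of the 27, was tested like the others and is left out of the text for a reason unrelated to its values. Lists were tested with limma's camera (limma 3.58.1, correlation preset at 0.01), adjusted over the 26 lists with enough measured genes within each comparison. Members were also adjusted over their list alone. The lists, comparisons, tests, alternatives and the rule for the genes to be named were chosen before the data were examined.

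Genes were named by that rule. For each comparison with untreated cells it takes the 6 largest rises and 6 largest falls, and for the others 4 and 4, among protein-coding genes with adjusted p under 0.05, a mean of at least 5 CPM and groups that do not overlap, which chance gives in 10% of genes for 3 against 3 libraries. Overlap was not asked of interactions. The rule adds up to 4 members of each list with the smallest adjusted p, and 18 genes fixed for the drugs and the tumour. The text names a part of the genes the rule takes, 283 of 1117 called values.

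The alternatives were RLE size factors, no filter beyond 1 count in any library, a stricter filter (1 CPM in at least 3 libraries), DESeq2 1.42.0 (Wald test, all libraries), a fit of the compared groups alone, the replicate number as a block, the 50 most counted genes left out, and each library of the compared groups left out in turn. For lists they were camera with an estimated correlation, limma's fry, RLE, the block and each library left out. Where a library is left out, the group keeps 2. Agreement between treatments that share the untreated libraries was set beside 20 simulations of unchanged groups. In each, all 18 libraries, the untreated ones included, were drawn from the means of the untreated libraries.

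The fit was tested on simulated data with the means and dispersions of these libraries, in which sets of 50 genes were changed by known factors. For STA9090 against untreated it recovered 6% of genes changed 1.25-fold, 56% at 1.5-fold, 86% at 2-fold and 94% at 3-fold, and called 4 unchanged genes among 15502 tested. For STA9090+PIK75 against PIK75 the shares were 14%, 60%, 88% and 94%, with 4 unchanged genes called among 15516. For the interaction of STA9090 with PIK75 they were 2%, 14%, 66% and 96%, with 9 called among 15538. Each gene had the same dispersion in all groups, and the changed genes had a mean of at least 1 CPM. The shares and false calls therefore do not describe groups that differ in spread, nor the shares changed genes of lower counts. Camera called a simulated list of 25 genes shifted by 0.25 on the log2 scale (adjusted p = 1.87e-24) and 0 of 25 unshifted lists. The simulated genes were drawn independently, so these list results do not show how often camera falsely calls lists of correlated genes. No library and no column of the table was left out.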

Results

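Gene expression was measured by RNA sequencing in NCI-H295R cells, a human adrenocortical carcinoma line that makes steroid hormones. Cells were untreated or were exposed for 48 h, at a stated 20 nM, to STA9090 (ganetespib, an inhibitor of the chaperone HSP90), PIK75 (a PI3K inhibitor), BGT226 (a PI3K and mTOR inhibitor), STA9090 with PIK75, or STA9090 with BGT226. The dose of each agent within a combination was not stated, and no vehicle was named for the untreated cells. Each of the 6 groups had 3 biological replicates, 18 libraries in all. The expected counts of a library summed to between 10.2 and 21.1 M. Group means were 13.1 ± 2.53 M for untreated cells, 13.8 ± 1.31 for STA9090, 12.8 ± 0.492 for PIK75, 14.6 ± 5.75 for BGT226, 12.9 ± 0.672 for STA9090+PIK75 and 13.8 ± 1.99 for STA9090+BGT226 (SD, n = 3). Of 58870 genes in the table, 15787 had enough counts to be tested.

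The single agents against untreated cells ask what each inhibitor does alone. Each combination was set against untreated cells, against each of its parts, and, as an interaction on the log2 scale, against the sum of its single effects, since the series' title asks about PI3K and HSP90 inhibition together. PIK75 and BGT226 were also compared with each other at the same stated dose and time, alone and with STA9090. Values after gene symbols and medians of lists are log2 fold changes unless a unit is given. Beside a list, the pair of counts adjusted over the list alone gives higher genes, then lower ones. Untreated libraries, measured the same way, were the background of every comparison with untreated cells.

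Libraries of a group lay together on the leading principal components, which carried 24.4%, 18.9% and 9.85% of the variance. STA9090 libraries overlapped untreated ones on the leading pair, and STA9090 replicate 1 stood apart on the third component, at 30.1 against 12 and 9.16 for the other STA9090 libraries. PIK75 replicate 3 stood apart there too, at -35.41 against -22.55 and -22.54 for the other PIK75 libraries. The 4 RNA polymerase III transcripts RN7SL1, RN7SL2, RN7SK and RPPH1 took 28.6% to 40.3% of the counts of a library, with group means from 32.3% ± 4.70 in untreated cells to 38.0% ± 2.26 with STA9090+PIK75. Mitochondrial mRNA took 4.71% to 10.7%. Of the list of fibroblast, endothelial and leukocyte markers, COL1A1 and CD14 alone had enough counts to be measured, too few to test the list.

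**Figure D1:**
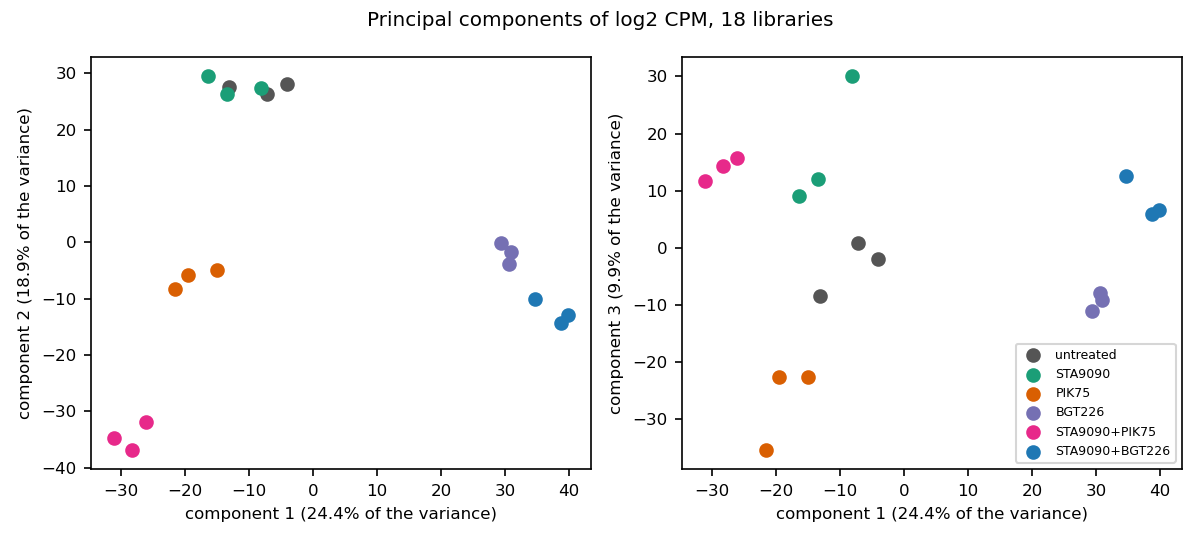
Principal components of log2 CPM (counts scaled to 1 M), each point 1 of 18 libraries coloured by group, with component 1 (24.4% of the variance) on both x axes and components 2 (18.9%) and 3 (9.85%) on the y axes. PIK75 and BGT226 libraries lie on opposite sides of component 1, with the untreated, STA9090 and STA9090+PIK75 libraries on the side of PIK75. STA9090 replicate 1 lies at 30.1 on component 3 and PIK75 replicate 3 at -35.41.

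The genes that recur below are identified by the IDs of the deposited table and by GENCODE 29 positions on hg38. They were HSP90AA1 (ENSG00000080824.18, chromosome 14, 102080738 to 102139699), CYP17A1 (ENSG00000148795.7, chromosome 10, 102830531 to 102837533), STAR (ENSG00000147465.11, chromosome 8, 38143649 to 38151265), HSD3B2 (ENSG00000203859.10, chromosome 1, 119414931 to 119423035), SPRY4 (ENSG00000187678.9, chromosome 5, 142310427 to 142326455), EGR1 (ENSG00000120738.8, chromosome 5, 138465490 to 138469315), HLA-B (ENSG00000234745.11, chromosome 6, 31269491 to 31357188), COL1A1 (ENSG00000108821.13, chromosome 17, 50183289 to 50201632) and CLSTN3 (ENSG00000139182.14, chromosome 12, 7129698 to 7158945).

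STA9090 alone changed few transcripts. HSP90AA1, which encodes the inducible form of the drug's target, rose from 182 ± 17.0 to 277 ± 44.5 CPM (SD, n = 3; log2 fold change 0.61, SE 0.0993, adjusted p = 0.00455). HLA-B, a molecule that presents antigens, fell from 38.0 ± 2.87 to 17.6 ± 2.48 CPM (log2 fold change -1.12, SE 0.115, adjusted p = 6.56e-05), with the caution that its reads are shared with near copies. The myotonic dystrophy kinase DMPK (-0.85 ± 0.101, SE) and GNAO1, a G protein subunit (-0.76 ± 0.0953), fell. Among other changes, the dystrophin gene DMD (0.93), the chemokine CCL22 (0.73) and the replication fork protein RADX (0.65) rose, and the actin-binding ABLIM1 (-0.81) and the ephrin EFNB1 (-0.76) fell.

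Of 24 measured heat shock chaperones, 7 rose and 0 fell with STA9090 (9 and 1 adjusted over the list alone, median 0.19, camera adjusted p = 4.61e-06, adjusted p = 0.0919 with an estimated correlation). The constitutive HSP90AB1 (0.09, adjusted p = 0.661) and the HSP70 gene HSPA1A (-0.08, adjusted p = 0.759, near-identical to HSPA1B) did not pass. ER chaperones moved the other way, with 3 of 18 lower (0 and 5 adjusted over the list alone, median -0.13, camera adjusted p = 0.00093, adjusted p = 0.0919 with an estimated correlation). HSPA5, the main ER chaperone, was at -0.34, a call that ended without untreated replicate 1 (-0.32) and without STA9090 replicate 2 (-0.34). In the list of the IGF2 locus and WNT targets, 4 of 15 fell (2 and 6 adjusted over the list alone, median -0.15, camera adjusted p = 0.00437, adjusted p = 0.0919 with an estimated correlation). The WNT feedback genes NKD1 (-0.47) and RNF43 (-0.44) were among these falls. Cytosolic ribosomal protein genes shifted up as a list with 1 of 36 passing alone (9 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 2.16e-07, adjusted p = 0.4 with an estimated correlation). Mitotic genes did so with 0 of 28 (0 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 0.00093, adjusted p = 0.26 with an estimated correlation). Smaller list shifts were found for proteasome subunits, with 1 of 27 higher (1 and 0 adjusted over the list alone, median 0.09, camera adjusted p = 0.0229, adjusted p = 0.489 with an estimated correlation). G1/S and replication genes shifted with 0 higher and 0 lower of 25 (1 and 1 adjusted over the list alone, median -0.09, camera adjusted p = 0.0496, adjusted p = 0.451 with an estimated correlation), down by camera. Neuroendocrine markers were lower in 2 of 7 (0 and 2 adjusted over the list alone, median -0.20, camera adjusted p = 0.0445, adjusted p = 0.24 with an estimated correlation). The proteasome call ended without untreated replicate 1 (adjusted p = 0.1), without untreated replicate 3 (adjusted p = 0.253), without STA9090 replicate 2 (adjusted p = 0.0763) and without STA9090 replicate 3 (adjusted p = 0.071), and fry, a test of the list's own members, did not make it. The G1/S call ended without untreated replicate 2 (adjusted p = 0.239), without STA9090 replicate 2 (adjusted p = 0.0763) and without STA9090 replicate 3 (adjusted p = 0.0609). The neuroendocrine call ended without untreated replicate 1 (adjusted p = 0.137), without untreated replicate 2 (adjusted p = 0.0551), without STA9090 replicate 2 (adjusted p = 0.0763) and without STA9090 replicate 3 (adjusted p = 0.0609). Without STA9090 replicate 2 camera called 5 lists, against 8 with all libraries. Steroidogenesis did not pass as a list, with 1 gene higher and 1 lower of 22 (1 and 1 adjusted over the list alone, median -0.01, camera adjusted p = 0.96, mean log2 fold change of the opposite sign at 0.0147). CYP17A1 stood at -0.07 (adjusted p = 0.695).

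With STA9090, 183 genes were higher and 265 lower, 19 and 13 of them by at least 2-fold. These counts moved by over 1.5 times without single libraries. They were 57 higher and 146 lower without untreated replicate 1, 96 and 141 without untreated replicate 2, and 56 and 76 without untreated replicate 3. They were 32 and 84 without STA9090 replicate 1, and the lower count was 172 without STA9090 replicate 2. In edgeR with the 2 compared groups alone in the fit, 0 were higher and 4 lower. That fit ended every gene call with STA9090 named here except those of HLA-B, DMPK and GNAO1. DESeq2 on all libraries called 233 and 397, and edgeR without a filter on low counts 369 and 400. In the fit of all libraries 2902 genes had an unadjusted p under 0.05 (789 expected by chance). That p uses the spread shared by all groups, which the fit of the 2 groups alone does not.

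PIK75 alone lowered genes of steroid synthesis. CYP17A1, the enzyme that opens the path to cortisol and androgens, fell from 263 ± 20.3 to 83.8 ± 2.92 CPM (SD, n = 3; log2 fold change -1.65, SE 0.0827, adjusted p = 3.39e-11). STAR, which carries cholesterol into mitochondria, fell from 357 ± 27.0 to 194 ± 9.06 CPM (log2 fold change -0.88, SE 0.0786, adjusted p = 1.36e-07). CYP11A1, which makes pregnenolone, fell too (-0.75 ± 0.0906, SE). The synuclein-binding protein gene SNCAIP rose by 2.23 ± 0.153, the tenascin TNXB, which shares sequence with a pseudogene copy and is uncertain here, by 2.06 ± 0.218, and CACNA1C, a calcium channel subunit, from 48.1 ± 0.799 to 159 ± 2.42 CPM. CUX2 (1.57), ACKR3 (1.5) and FOSL2 (1.48) also rose. HEXIM1, an inhibitor of transcription elongation (-1.51 ± 0.0844), fell, as did C1S (-1.62), FAM166B (-1.56), MXRA7 (-1.34) and TUBB4A (-1.32).

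Of 22 measured genes of steroidogenesis and adrenocortical identity, 13 fell and 1, the angiotensin receptor AGTR1 (0.69), rose with PIK75 (1 and 13 adjusted over the list alone, median -0.53, camera adjusted p = 1.78e-10). Cholesterol synthesis genes fell in 11 of 24 cases, including EBP (-0.65), FDPS (-0.58) and DHCR7 (-0.57) (0 and 13 adjusted over the list alone, median -0.22, camera adjusted p = 1.95e-05). Fatty acid synthesis genes fell in 6 of 11, among them FADS2 (-0.54), SREBF1 (-0.51) and SCD (-0.44) (0 and 6 adjusted over the list alone, median -0.27, camera adjusted p = 0.00236). NRF2 targets, which serve antioxidant defence, fell in 9 of 17 and rose in 1, with OSGIN1 at -1.04 and GCLC at -0.53 (1 and 10 adjusted over the list alone, median -0.39, camera adjusted p = 1.95e-05). The list of the IGF2 locus and WNT targets went up, with 6 higher and 1 lower of 15 (9 and 1 adjusted over the list alone, median 0.22, camera adjusted p = 0.000131). Its risen members included the WNT inhibitors APCDD1 (0.94), ZNRF3 (0.67) and AXIN2 (0.38), which act against the pathway.

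Mitotic genes rose in 12 of 28, such as DLGAP5 (0.54), TTK (0.52) and CCNB2 (0.49) (14 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 2.29e-05, adjusted p = 0.0776 with an estimated correlation). Of 25 G1/S genes 4 fell, such as RRM2 (-0.88) and CCNE1 (-0.54) (0 and 4 adjusted over the list alone, median -0.12, camera adjusted p = 0.00323, adjusted p = 0.208 with an estimated correlation). Proteasome subunits fell in 13 of 27, with PSMD11 at -0.62 and PSMB7 at -0.50 (0 and 19 adjusted over the list alone, median -0.29, camera adjusted p = 7.54e-08, adjusted p = 0.0639 with an estimated correlation). Genes of hypoxia and glycolysis fell in 7 of 18, with LDHA at -0.88 and PFKFB3 at -0.60 (0 and 7 adjusted over the list alone, median -0.23, camera adjusted p = 0.000704, adjusted p = 0.21 with an estimated correlation). Heat shock chaperones fell in 7 and rose in 2 of 24, the small chaperones CRYAB (-1.50) and HSPB8 (-1.04) among the falls (2 and 10 adjusted over the list alone, median -0.18, camera adjusted p = 0.0121, adjusted p = 0.21 with an estimated correlation). Lysosome and autophagy genes fell in 7 and rose in 1 of 22, with GABARAPL1 at -0.56 and CTSA at -0.43 (3 and 9 adjusted over the list alone, median -0.22, camera adjusted p = 0.00551, adjusted p = 0.241 with an estimated correlation). This call ended without untreated replicate 2 (adjusted p = 0.0534). The list of FOXO targets (7 higher, 4 lower of 19, camera adjusted p = 0.372) did not pass.

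PIK75 raised 1340 genes and lowered 1607, 219 and 138 of them by at least 2-fold, by edgeR's quasi-likelihood test. Without untreated replicate 1 the rise count was 853, and with the 2 compared groups alone in the fit 1066 genes were lower.

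BGT226 alone changed more genes, in both directions. The RNA of C6orf48, which hosts small nucleolar RNAs, rose from 13.6 ± 1.07 to 67.6 ± 0.840 CPM (SD, n = 3; log2 fold change 2.31, SE 0.0921, adjusted p = 1.61e-12). TXNIP, a thioredoxin inhibitor, rose by a log2 fold change of 1.94 ± 0.0848 (SE), and SPRY4, a feedback inhibitor of the ERK pathway, from 5.42 ± 0.818 to 17.3 ± 0.796 CPM. ACAT2, an enzyme of sterol synthesis, fell from 86.5 ± 5.22 to 28.2 ± 1.77 CPM (log2 fold change -1.62, SE 0.0822, adjusted p = 5.63e-11), as did CHAC1, a target of the stress factor ATF4 (-2.11 ± 0.183). FAXDC2 (1.86), CUX2 (1.72) and CREBRF (1.55) also rose. FABP3 (-1.85), CCL22 (-1.59) and MYOT (-1.54) fell.

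Sterol and lipid genes fell broadly with BGT226. Of 24 cholesterol synthesis genes 20 fell, with FDPS at -1.54 and LSS at -1.40 (0 and 20 adjusted over the list alone, median -0.74, camera adjusted p = 4.29e-34). Fatty acid synthesis genes fell in 10 of 11, with ACLY at -1.43 and SCD at -1.28 (0 and 10 adjusted over the list alone, median -0.71, camera adjusted p = 3.08e-17). All 27 measured proteasome subunits fell, among them PSMD11 (-0.95) and PSMB2 (-0.84) (0 and 27 adjusted over the list alone, median -0.66, camera adjusted p = 9.94e-29). G1/S genes fell in 20 of 25, with PCNA at -0.62 and E2F1 at -0.60 (0 and 21 adjusted over the list alone, median -0.40, camera adjusted p = 1.3e-11). Mitotic genes fell in 19 of 28, with CDC20 at -0.83 and AURKA at -0.81 (0 and 19 adjusted over the list alone, median -0.35, camera adjusted p = 7.34e-10). ATF4 targets fell in 14 and rose in 3 of 21, the falls including the serine and asparagine synthesis genes PSAT1 (-1.24) and ASNS (-1.53) (4 and 16 adjusted over the list alone, median -0.86, camera adjusted p = 1.57e-10). NRF2 targets fell in 12 of 17, with SLC7A11 at -1.06 and NQO1 at -0.98 (1 and 13 adjusted over the list alone, median -0.54, camera adjusted p = 1.04e-08).

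FOXO targets and receptor genes rose in 11 and fell in 2 of 19, including FOXO3 (1.2), FOXO1 (1.13) and KLHL24 (0.96) (13 and 2 adjusted over the list alone, median 0.29, camera adjusted p = 2.54e-10). ERK feedback genes rose in 10 of 12, with ETV4 at 1.01 and DUSP4 at 0.90 (11 and 0 adjusted over the list alone, median 0.63, camera adjusted p = 1.04e-11). Immediate early genes rose in 10 and fell in 2 of 19, with EGR1 going from 13.5 ± 1.22 to 34.6 ± 2.65 CPM (10 and 3 adjusted over the list alone, median 0.45, camera adjusted p = 0.000564, adjusted p = 0.164 with an estimated correlation). Ribosomal protein and elongation factor genes rose in 20 and fell in 1 of 36, with EEF2 at 1.07 and RPL5 at 0.71 (23 and 2 adjusted over the list alone, median 0.37, camera adjusted p = 6.93e-07, adjusted p = 0.195 with an estimated correlation). Heat shock chaperones fell in 12 of 24, STIP1 (-0.68) and FKBP4 (-0.58) among them (0 and 12 adjusted over the list alone, median -0.27, camera adjusted p = 0.000237). Glycolysis genes fell in 11 of 18, such as PKM (-0.82) and LDHA (-0.69) (0 and 11 adjusted over the list alone, median -0.31, camera adjusted p = 0.000256, adjusted p = 0.152 with an estimated correlation).

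Steroidogenesis split with BGT226, 10 genes falling and 5 rising of 22 (5 and 10 adjusted over the list alone, median -0.21, camera adjusted p = 0.00975, adjusted p = 0.195 with an estimated correlation). CYP17A1 fell to 104 ± 1.87 CPM (-1.34), STAR (-0.73) and CYP11A1 (-0.49) also fell. HSD3B2, which makes progesterone, rose by 0.34, a call that ended without untreated replicate 1 (0.28) and without untreated replicate 3 (0.25). ER chaperones rose in 6 and fell in 1 of 18, with DNAJB9 at 0.75 and XBP1 at 0.40 (7 and 1 adjusted over the list alone, median 0.17, camera adjusted p = 0.0434, adjusted p = 0.189 with an estimated correlation). This list call ended without untreated replicate 2 (adjusted p = 0.0788) and without BGT226 replicate 3 (adjusted p = 0.0597). Several other genes changed, among them CDKN1A, the p21 cell cycle inhibitor (-1.38), and the translation repressor EIF4EBP1 (-1.04). So did the BCL2-family genes HRK (1.06), BMF (0.99) and BCL2L11 (0.54), which promote apoptosis, and the tumour-related IGF2 (0.58), DLK1 (0.68) and MYC (0.53). IGF2 values also carry reads of INS-IGF2 readthrough transcripts if the counting split them. BGT226 raised 2028 genes and lowered 2485, 276 and 149 by at least 2-fold.

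**Figure D2:**
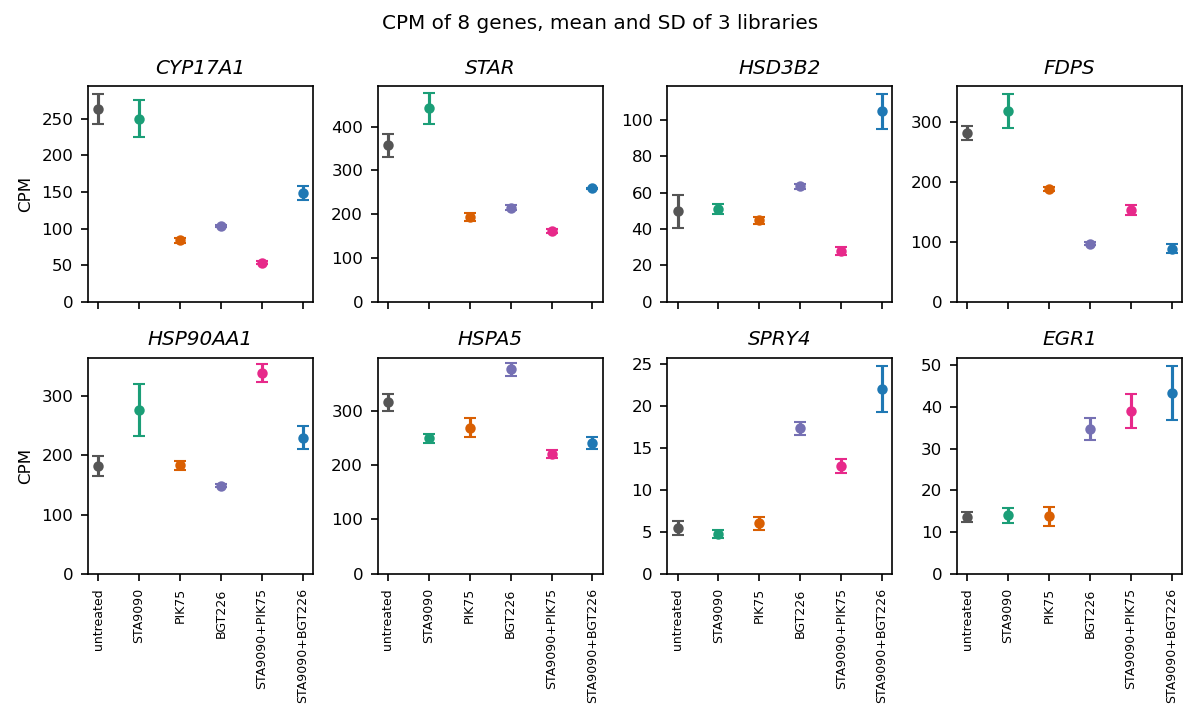
CPM of 8 genes in the 6 groups, each point the mean and each bar the SD of 3 libraries, on linear axes from 0. CYP17A1 stood at 263 ± 20.3 in untreated cells and 53.4 ± 2.28 with STA9090+PIK75, and HSD3B2 at 27.7 ± 2.17 and 105 ± 9.52 in the combinations.

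PIK75 and BGT226 were compared at the same stated dose and time, and differed in 5045 genes, 2603 higher and 2442 lower with PIK75. The ATF4 target CHAC1 (1.96 ± 0.186, log2 fold change of PIK75 over BGT226 and SE), SNCAIP (2.48) and the muscle gene MYOT (2.19) were higher with PIK75. The arginine synthesis gene ASS1 (-2.23 ± 0.176), FAXDC2 (-2.10), the ERK-induced factor ETV4 (-1.99) and C6orf48 (-1.94) were lower. Mitotic genes were higher with PIK75 in 26 of 28, with CDC20 at 1.16 and BIRC5 at 0.96 (26 and 0 adjusted over the list alone, camera adjusted p = 2.2e-19). Cholesterol genes were higher in 19 of 24, with LSS at 1.11 (20 and 1 adjusted over the list alone, camera adjusted p = 8.8e-14). Fatty acid genes were higher in 7 of 11, with ACLY at 1.16 (7 and 0 adjusted over the list alone, camera adjusted p = 4.16e-07). ATF4 targets were higher in 16 and lower in 4 of 21, with ASNS at 1.79 (16 and 4 adjusted over the list alone, camera adjusted p = 9.43e-10). ERK feedback genes were lower with PIK75 in 10 and higher in 1 of 12, with SPRY4 at -1.53 (1 and 10 adjusted over the list alone, camera adjusted p = 2.45e-09). FOXO targets were lower in 11 and higher in 3 of 19, with TXNIP at -1.64 (5 and 11 adjusted over the list alone, camera adjusted p = 2.53e-06). Of the fixed genes CDKN1A (1.10) and MTOR (0.53) were higher with PIK75. IGF2 (-0.65), HSD3B2 (-0.50) and CYP17A1 (-0.31) were lower. Camera called 14 of 26 lists between the agents, 6 of them with an estimated correlation.

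Called in the same direction by PIK75 and by BGT226 were 393 higher and 649 lower genes, against 172 and 253 for independent lists. The count was 0 in 20 simulations of unchanged groups, all drawn from the untreated means and sharing simulated untreated libraries. Almost no gene is called where none was changed, so these counts of 0 do not weigh the overlaps. In the data a further 270 genes went opposite ways. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.424 (simulated 0.499) with a covariance of 0.1 (simulated 0.0300, difference 0.0701). STA9090 and PIK75 shared 36 higher and 70 lower genes (15.5 and 27.0 for independent lists, simulated 0) with 59 opposite. Their correlation was 0.258 (simulated 0.489) and their covariance 0.0457 (simulated 0.0296, difference 0.0162). STA9090 and BGT226 shared 46 and 33 (23.5 and 41.7 for independent lists, simulated 0) with 121 opposite. No count of opposite genes for independent lists was made in any pair. Between STA9090 and BGT226 opposite genes outnumbered shared ones. The correlation here was 0.202 (simulated 0.499) and the covariance 0.0373 (simulated 0.0301, difference 0.00720). The 3 untreated libraries cannot be divided into parts of 2, so part of any excess may come from the shared controls. Without untreated replicate 1, 2 or 3 in turn, STA9090 and PIK75 shared 13, 19 and 18 higher and 42, 41 and 25 lower genes. In the same order, STA9090 and BGT226 shared 17, 29 and 14 higher and 26, 19 and 15 lower genes. PIK75 and BGT226 shared 234 higher genes without untreated replicate 1.

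**Figure D3:**
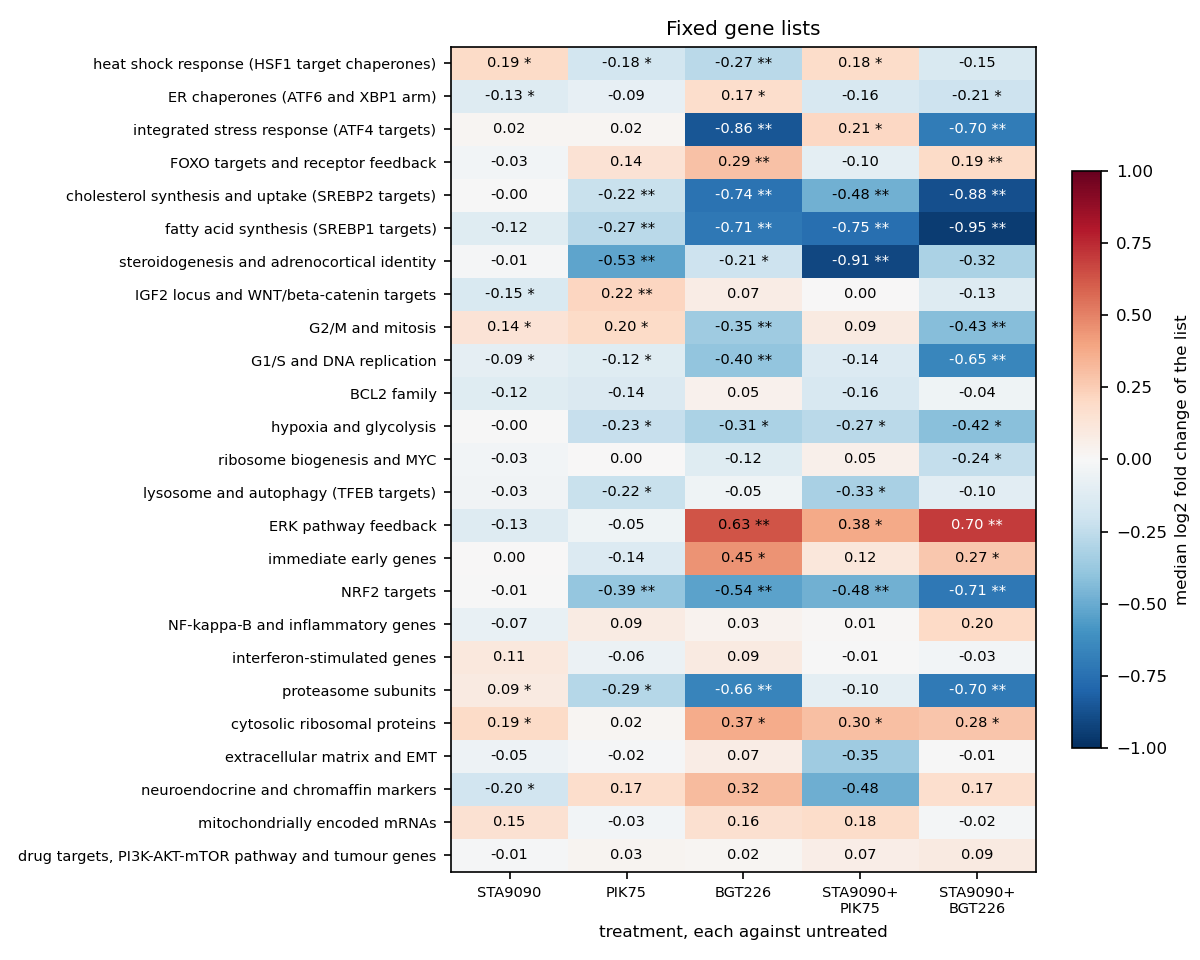
Median log2 fold change of 25 fixed gene lists (26 were tested) in the 5 treatments against untreated, coloured from -1 to 1, with 1 asterisk where camera's adjusted p was under 0.05 and 2 where it was so with an estimated correlation too. Steroidogenesis reached -0.91 with STA9090+PIK75, and proteasome subunits -0.66 with BGT226.

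STA9090+PIK75 lowered genes of steroid synthesis below their levels with either agent. CYP17A1 fell from 263 ± 20.3 CPM in untreated cells to 53.4 ± 2.28 (SD, n = 3; log2 fold change -2.30, SE 0.0851, adjusted p = 3.52e-13), and was below its level with PIK75 alone (-0.65 ± 0.0834, SE). CYP11A1 (-1.29 ± 0.0918) and STAR (-1.14 ± 0.0791) fell, and HSD3B2 fell from 49.9 ± 9.07 to 27.7 ± 2.17 CPM. HSP90AA1 rose to 339.6 ± 15.2 CPM (log2 fold change 0.90, SE 0.0996, adjusted p = 5.94e-07). The collagen gene COL1A1 (-3.50 ± 0.246), FAM166B (-3.23 ± 0.148) and the basement membrane gene COL18A1 (-2.25 ± 0.1) fell, with TMPRSS9 (-2.33) and the crosslinking enzyme TGM2 (-2.25) also lower. TNXB (2.50; uncertain), SNCAIP (2.2), TSTA3 (2.10), the transcription factor MYB (1.85), TMEM163 (1.81) and COL7A1 (1.62) rose.

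Of 22 measured steroidogenesis genes 21 fell and 0 rose against untreated cells, SCARB1, the lipoprotein receptor that supplies cholesterol, at -1.58 (0 and 21 adjusted over the list alone, median -0.91, camera adjusted p = 1.96e-21). Cholesterol synthesis genes fell in 16 of 24, with EBP at -1.22 (0 and 19 adjusted over the list alone, median -0.48, camera adjusted p = 1.15e-08). Fatty acid genes fell in 9 of 11, with SCD at -1.04 and SREBF1 at -1.03 (0 and 11 adjusted over the list alone, median -0.75, camera adjusted p = 1.15e-08). NRF2 targets fell in 12 of 17, with OSGIN1 at -1.22 and, among the 2 that rose, the cystine transporter SLC7A11 at 0.99 (2 and 12 adjusted over the list alone, median -0.48, camera adjusted p = 0.00203). Heat shock chaperones rose in 10 and fell in 1 of 24, with HSPH1 at 1.09 and CHORDC1 at 0.94 (10 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.0124, adjusted p = 0.269 with an estimated correlation). ATF4 targets rose in 9 and fell in 2 of 21, with ASNS at 1.10 (9 and 2 adjusted over the list alone, median 0.21, camera adjusted p = 0.0043, adjusted p = 0.269 with an estimated correlation). ERK feedback genes rose in 6 and fell in 2 of 12, with SPRY4 at 1.24 (7 and 2 adjusted over the list alone, median 0.38, camera adjusted p = 0.0124, adjusted p = 0.0914 with an estimated correlation). Ribosomal protein genes rose in 22 of 36, with RPS23 at 0.67 (24 and 0 adjusted over the list alone, median 0.30, camera adjusted p = 0.000583, adjusted p = 0.411 with an estimated correlation). Hypoxia and glycolysis genes fell in 9 of 18, with LDHA at -1.43 (0 and 10 adjusted over the list alone, median -0.27, camera adjusted p = 0.0052, adjusted p = 0.299 with an estimated correlation). Lysosome genes fell in 12 and rose in 1 of 22, with CTSD at -0.91 (1 and 13 adjusted over the list alone, median -0.33, camera adjusted p = 0.00203, adjusted p = 0.269 with an estimated correlation).

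Lists that did not pass against untreated cells held single genes that did. They included the IGF2 locus RNA H19 (-1.67), IGF2 (-0.58), the ribonucleotide reductase RRM2 (-1.22) and CDKN1A (-1.07). Others were the apoptosis promoter BIK (1.12), the vesicle protein SYP (-1.17), the ER chaperone HSPA5 (-0.51) and the integrin ITGB1 (-0.62). The list of the IGF2 locus and WNT targets had 3 higher and 4 lower of 15, a median near 0 and a negative mean (3 and 4 adjusted over the list alone, median 0.000404, camera adjusted p = 0.869, mean log2 fold change -0.19). STA9090+PIK75 raised 2886 genes and lowered 3170 against untreated cells, 548 and 507 by at least 2-fold.

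Adding STA9090 to PIK75 raised 1784 genes and lowered 2209 against PIK75 alone. EGR1, an immediate early transcription factor, rose from 13.7 ± 2.25 to 39.0 ± 4.02 CPM (log2 fold change 1.51, SE 0.130, adjusted p = 9.24e-08), FOSB by a log2 fold change of 1.43 ± 0.141 (SE) and the cancer/testis antigen CT45A1, 1 of several near-identical copies and so uncertain, by 1.3. COL1A1 (-2.87), CUX2 (-1.85), FAM166B (-1.67) and ABLIM1 (-1.63) fell. Heat shock chaperones rose in 14 of 24, with HSP90AA1 at 0.89 and STIP1 at 0.71 (16 and 0 adjusted over the list alone, camera adjusted p = 1.11e-08). Steroidogenesis genes fell in 18 and rose in 1 of 22, with the sulfotransferase SULT2A1 at -1.09 and AGTR1 at -1.02 (1 and 18 adjusted over the list alone, camera adjusted p = 8.43e-10). Fatty acid genes fell in 8 of 11, with FASN at -0.94 (0 and 8 adjusted over the list alone, camera adjusted p = 1.09e-05). WNT and IGF2 genes fell in 10 of 15, with IGF2 at -0.51 and NKD1 at -0.37 (0 and 11 adjusted over the list alone, camera adjusted p = 0.00122). ERK feedback genes rose in 7 of 12, with SPRY4 at 1.10 and DUSP5 at 0.46 (9 and 0 adjusted over the list alone, camera adjusted p = 0.00133). Camera called 13 of 26 lists in this step, 5 of them with an estimated correlation.

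Against STA9090 alone, STA9090+PIK75 raised 2787 genes and lowered 3127. CYP17A1 fell from 250.4 ± 25.7 to 53.4 ± 2.28 CPM (log2 fold change -2.23, SE 0.0849, adjusted p = 6.3e-13), as did CYP11A1 (-1.51) and STAR (-1.45). In all, 20 of 22 steroidogenesis genes fell (0 and 20 adjusted over the list alone, camera adjusted p = 3.7e-23). TNXB (2.92; uncertain), MYB (1.95) and TSTA3 (1.73) rose. FAM166B (-3.60), COL1A1 (-3.10), TMPRSS9 (-2.50) and TGM2 (-2.23) fell. Cholesterol genes fell in 19 and rose in 1 of 24, with EBP at -1.15 (1 and 19 adjusted over the list alone, camera adjusted p = 3.04e-10). Fatty acid genes fell in 11 of 11, with SCD at -0.86 (0 and 11 adjusted over the list alone, camera adjusted p = 4.27e-08). Of the 9 lists camera called, 5 passed with an estimated correlation.

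The interaction of STA9090 with PIK75 asks where the combination departed from the sum of the single effects. EGR1 stood at 13.5 ± 1.22 CPM in untreated cells, 14.0 ± 1.77 with STA9090, 13.7 ± 2.25 with PIK75 and 39.0 ± 4.02 with both (SD, n = 3), an excess of 1.47 ± 0.191 over the sum on the log2 scale (SE; adjusted p = 0.00013). SPRY4 went 5.42, 4.73, 5.99 and 12.8 CPM in the same order (1.3 ± 0.2). FOSB (4.46, 5.16, 4.29 and 11.5 CPM, 1.22) likewise exceeded the sum. COL1A1 lay below it, at 9.21, 7.07, 5.99 and 0.799 CPM (-2.47 ± 0.323), and so did FAM166B (17.4, 22.6, 5.88 and 1.85 CPM, -2.04). Both fell further in the combination than the sum of their single effects. MUCL1 (5.94, 6.91, 8.66 and 3.48 CPM, -1.51) and DMD (5.77, 10.9, 10.9 and 7.42 CPM, -1.47) also lay below the sum. Each stood higher with either agent alone than with both.

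Steroidogenesis genes lay below the sum in 11 and above it in 0 of 22 cases (0 and 16 adjusted over the list alone, camera adjusted p = 2.09e-10). CYP17A1 was at 263, 250.4, 83.8 and 53.4 CPM (-0.58) and CYP11A1 at 322, 374, 192 and 132 (-0.76). Fatty acid genes lay below in 6 of 11 (0 and 6 adjusted over the list alone, camera adjusted p = 0.000147). ERK feedback genes lay above in 6 of 12 (8 and 0 adjusted over the list alone, camera adjusted p = 7.22e-05). Mitotic genes lay below in 9 of 28 (0 and 11 adjusted over the list alone, camera adjusted p = 2.75e-06, adjusted p = 0.0581 with an estimated correlation). Cholesterol genes lay below in 7 of 24 (1 and 11 adjusted over the list alone, camera adjusted p = 0.000207, adjusted p = 0.0581 with an estimated correlation). Heat shock chaperones lay above in 6 of 24 (6 and 0 adjusted over the list alone, camera adjusted p = 0.00461, adjusted p = 0.191 with an estimated correlation). ATF4 targets lay above in 5 and below in 1 of 21 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0044, adjusted p = 0.366 with an estimated correlation). The heat shock call ended without STA9090 replicate 2 (adjusted p = 0.0613). Without untreated replicate 3 camera called 11 lists here, against 7 with all libraries. In all, 559 genes lay above the sum and 904 below it, 69 and 139 by at least 2-fold. Without STA9090+PIK75 replicate 1 the count above was 344, and with the 4 groups of the interaction alone in the fit the counts were 294 and 515.

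**Figure D4:**
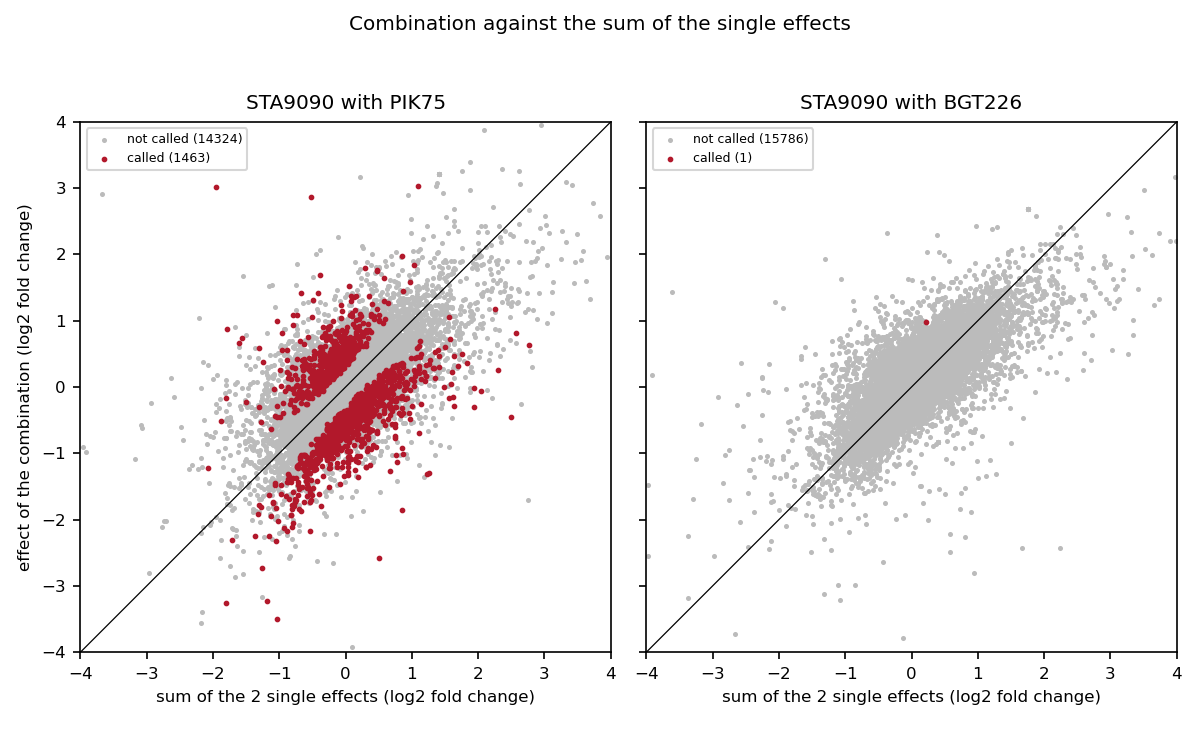
Effect of each combination (y, log2 fold change against untreated) against the sum of its single effects (x, log2 fold change), each point 1 gene, with the line of equality. Red points passed the interaction test, 1463 genes with PIK75 and 1 with BGT226, and 36 and 34 genes lie outside the drawn range of -4 to 4.

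With STA9090+BGT226, C6orf48 rose from 13.6 ± 1.07 to 73.2 ± 7.48 CPM (SD, n = 3; log2 fold change 2.42, SE 0.0919, adjusted p = 5.99e-13), TXNIP by a log2 fold change of 2.10 ± 0.0849 (SE), and SPRY4 to 22.0 ± 2.72 CPM (2.01 ± 0.12), with FAXDC2 (2.03), CUX2 (1.82) and LETMD1 (1.80). CHAC1 (-2.09 ± 0.182), the fatty acid carrier FABP3 (-1.86) and the glutamate transporter SLC1A3 (-1.79) fell. HSD3B2 rose from 49.9 ± 9.07 to 105 ± 9.52 CPM (log2 fold change 1.06, SE 0.0969, adjusted p = 6.28e-08), while CYP17A1 fell to 149 ± 9.27 CPM (log2 fold change -0.82, SE 0.0805, adjusted p = 1.65e-07). HSP90AA1 rose by 0.34, a call that ended without untreated replicate 2 (0.26) and without STA9090+BGT226 replicate 2 (0.27).

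Of 24 cholesterol genes 19 fell and 1 rose against untreated cells, with EBP at -1.68 and FDPS at -1.67 (1 and 21 adjusted over the list alone, median -0.88, camera adjusted p = 1.76e-24). Of 11 fatty acid genes 10 fell, with SCD at -1.63 (0 and 10 adjusted over the list alone, median -0.95, camera adjusted p = 7.23e-17). Proteasome subunits fell in 26 of 27, with PSMB2 at -1.0 (0 and 27 adjusted over the list alone, median -0.70, camera adjusted p = 7.14e-23). Among G1/S genes 22 of 25 fell, with RRM2 at -1.21 and E2F1 at -1.11 (0 and 22 adjusted over the list alone, median -0.65, camera adjusted p = 8.53e-21). Among mitotic genes 19 fell and 1 rose of 28, with CDC20 at -0.92 (1 and 19 adjusted over the list alone, median -0.43, camera adjusted p = 3.64e-09). NRF2 targets fell in 13 of 17, with NQO1 at -0.97 (0 and 13 adjusted over the list alone, median -0.71, camera adjusted p = 1.88e-08). ATF4 targets fell in 15 and rose in 3 of 21, with ASNS at -1.61 (3 and 15 adjusted over the list alone, median -0.70, camera adjusted p = 5.47e-08). FOXO targets rose in 9 and fell in 2 of 19, with FOXO1 at 1.23 (9 and 2 adjusted over the list alone, median 0.19, camera adjusted p = 3.49e-07). ERK feedback genes rose in 11 of 12, with ETV4 at 1.09 (11 and 0 adjusted over the list alone, median 0.70, camera adjusted p = 1.35e-10).

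ER chaperones fell in 9 of 18 with STA9090+BGT226, HYOU1 (-0.52) and PDIA6 (-0.44) among them (0 and 9 adjusted over the list alone, median -0.21, camera adjusted p = 0.00875, adjusted p = 0.0937 with an estimated correlation). Ribosomal protein genes rose in 19 and fell in 1 of 36, with EEF2 at 1.13 (20 and 2 adjusted over the list alone, median 0.28, camera adjusted p = 0.000101, adjusted p = 0.348 with an estimated correlation). Immediate early genes rose in 9 and fell in 3 of 19, with EGR1 at 1.68 (11 and 3 adjusted over the list alone, median 0.27, camera adjusted p = 0.00736, adjusted p = 0.289 with an estimated correlation). Hypoxia genes fell in 11 of 18, with LDHA at -1.02 (0 and 11 adjusted over the list alone, median -0.42, camera adjusted p = 0.000495, adjusted p = 0.163 with an estimated correlation). Ribosome biogenesis genes fell in 10 and rose in 2 of 20, with NOP2 at -0.64 (2 and 10 adjusted over the list alone, median -0.24, camera adjusted p = 0.0177, adjusted p = 0.0698 with an estimated correlation). Steroidogenesis (12 lower, 5 higher of 22, camera adjusted p = 0.0615) and heat shock (4 higher, 10 lower of 24, camera adjusted p = 0.151) did not pass as lists. CDKN1A (-1.65), EIF4EBP1 (-1.34) and the survival gene BCL2L1 (-0.52) fell. EGFR (1.16), HRK (0.88) and IGF2 (0.40) rose. STA9090+BGT226 raised 3059 genes and lowered 3228, 598 and 310 by at least 2-fold.

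Adding STA9090 to BGT226 changed 424 genes, 156 higher and 268 lower, 11 and 14 by at least 2-fold. HSD3B2 rose from 63.5 ± 1.2 to 105 ± 9.52 CPM (log2 fold change 0.72, SE 0.0955, adjusted p = 0.000277), CYP17A1 from 104 ± 1.87 to 149 ± 9.27 CPM (log2 fold change 0.52, SE 0.0811, adjusted p = 0.00141) and HSP90AA1 by a log2 fold change of 0.63 ± 0.0995 (SE), with the adhesion protein BCAM (0.77) and the chromatin protein HMGA1 (0.75) also higher. HLA-B (-1.26 ± 0.113) and HLA-C (-1.23 ± 0.104) fell, as did the histone gene HIST2H2AA3 (-1.25), all 3 uncertain because near copies share their reads. ER chaperones fell in 11 of 18 (0 and 13 adjusted over the list alone, camera adjusted p = 6.46e-23), HSPA5 going from 376 ± 12.3 to 241 ± 11.3 CPM (-0.65 ± 0.0755), with DNAJB9 at -0.81 and XBP1 at -0.61. G1/S genes fell in 10 of 25, with RRM2 at -0.59 and E2F1 at -0.51 (1 and 17 adjusted over the list alone, camera adjusted p = 5.73e-15). Heat shock chaperones rose in 4 of 24 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00531, adjusted p = 0.179 with an estimated correlation). Camera called 5 lists in this step, 2 of them with an estimated correlation.

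These counts for STA9090 added to BGT226 moved with the fit and with each library. DESeq2 called 148 higher and 441 lower, 25.1% higher against 36.8% in edgeR. With the 2 compared groups alone edgeR called 526 and 808, and without a filter on low counts 348 and 479. Without BGT226 replicate 1 the counts were 37 higher and 105 lower, without replicate 2 they were 35 and 99, and without replicate 3 they were 39 and 122. Without STA9090+BGT226 replicate 1 the lower count was 135, without replicate 2 the counts were 55 and 110, and without replicate 3 they were 51 and 157.

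Against STA9090 alone, STA9090+BGT226 raised 3078 genes and lowered 3300. C6orf48 (2.48 ± 0.0925, log2 fold change and SE), FAXDC2 (2.44), CUX2 (2.39) and SPRY4 (2.21) rose. CHAC1 (-2.30) and ACAT2 (-1.94 ± 0.0821) fell. Cholesterol genes fell in 21 and rose in 1 of 24, with FDPS at -1.84 (1 and 21 adjusted over the list alone, camera adjusted p = 8.54e-25). The 27 proteasome subunits all fell (0 and 27 adjusted over the list alone, camera adjusted p = 3.47e-27). ERK feedback genes rose in 11 of 12 (11 and 0 adjusted over the list alone, camera adjusted p = 1.53e-12). Heat shock chaperones fell in 14 of 24, with STIP1 at -0.79 (0 and 14 adjusted over the list alone, camera adjusted p = 0.00021). Of the 13 lists camera called, 10 passed with an estimated correlation.

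The interaction of STA9090 with BGT226 passed for 1 gene. CLSTN3, a calsyntenin of synapses, stood at 58.2 ± 1.84 CPM in untreated cells, 50 ± 3.33 with STA9090, 78.7 ± 3.01 with BGT226 and 114 ± 9.83 with both (SD, n = 3; log2 fold change 0.76, SE 0.104, adjusted p = 0.00699). Its call ended without untreated replicate 3 (0.73), without BGT226 replicate 1 (0.74) and without BGT226 replicate 3 (0.75). By edgeR, 1490 genes had an unadjusted p under 0.05 (789 expected by chance). DESeq2 called 19 above the sum and 27 below (41.3% above, against 100% in edgeR), and edgeR without a filter on low counts 82 and 187. The edgeR counts above and below were 3 and 3 without untreated replicate 2, 3 above without STA9090 replicate 1, and 2 above without STA9090 replicate 3. The count above was 0 without untreated replicate 3, BGT226 replicate 1 or BGT226 replicate 3. ER chaperones lay below the sum as a list with 0 of 18 passing alone (0 and 4 adjusted over the list alone, median -0.25, camera adjusted p = 4.18e-07). Camera called 9 lists for this interaction, with the ER chaperones alone passing with an estimated correlation.

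The 2 combinations differed from each other in 6836 genes, 3306 higher and 3530 lower with STA9090+PIK75. ASNS, which makes asparagine, stood at 62.2 ± 0.690 CPM with PIK75 in the pair and 9.56 ± 2.29 with BGT226 (SD, n = 3; log2 fold change 2.71, SE 0.134, adjusted p = 5.95e-12). CHAC1 was also higher (2.27 ± 0.181, SE). COL1A1 (-3.30), FAM166B (-3.05), the membrane scaffold AHNAK (-2.83) and COL18A1 (-2.52) were lower with PIK75. Steroidogenesis genes were lower in 18 and higher in 1 of 22, with HSD3B2 at -1.91, CYP17A1 at -1.48 and MC2R at -2.10 (1 and 18 adjusted over the list alone, camera adjusted p = 1.89e-11). ATF4 targets were higher in 15 and lower in 1 of 21, with PHGDH at 1.91 (15 and 2 adjusted over the list alone, camera adjusted p = 1.49e-13). Proteasome subunits were higher in 25 of 27, with PSMB6 at 1.29 (25 and 0 adjusted over the list alone, camera adjusted p = 1.49e-13). Heat shock chaperones were higher in 16 and lower in 3 of 24, with STIP1 at 0.99 (16 and 3 adjusted over the list alone, camera adjusted p = 0.000277).

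G1/S genes were higher with STA9090+PIK75 than with STA9090+BGT226 in 21 and lower in 1 of 25 (22 and 1 adjusted over the list alone, camera adjusted p = 3.11e-11). Mitotic genes were higher in 20 of 28, with CDC20 at 1.19 (22 and 0 adjusted over the list alone, camera adjusted p = 2.19e-09). FOXO targets were lower in 10 and higher in 2 of 19, with TXNIP at -1.71 and FOXO1 at -1.47 (2 and 10 adjusted over the list alone, camera adjusted p = 4.16e-06). ERK feedback genes were lower in 7 and higher in 1 of 12 (1 and 7 adjusted over the list alone, camera adjusted p = 0.00274). Of the 11 lists camera called between the combinations, 10 passed with an estimated correlation.

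**Figure D5:**
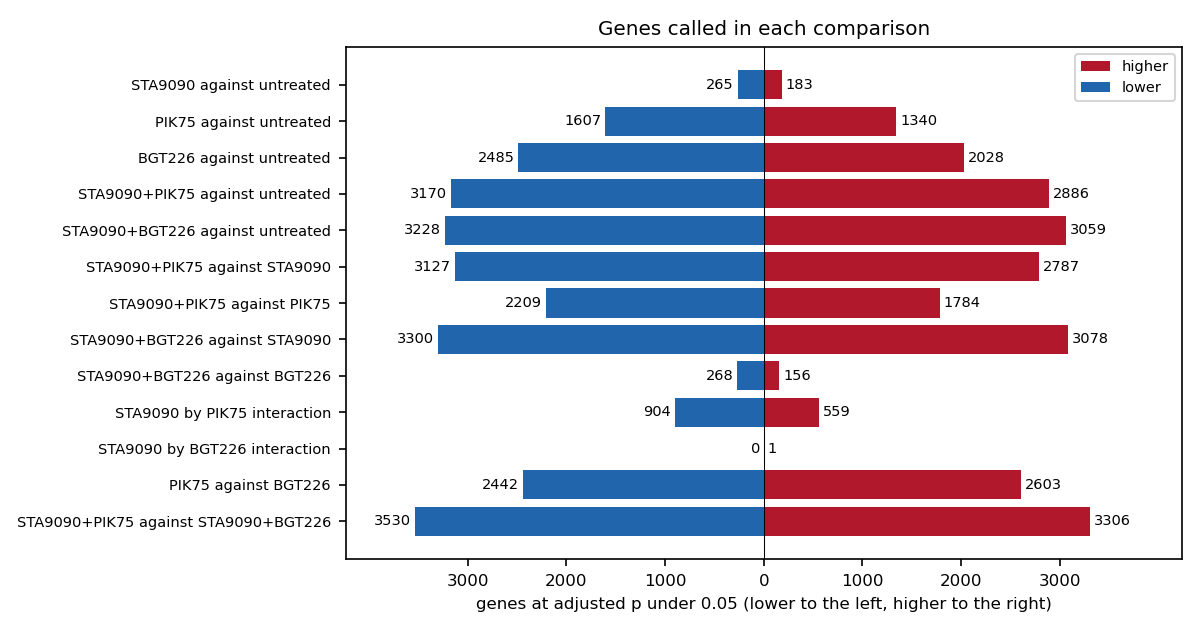
Genes passing edgeR's quasi-likelihood test (adjusted p under 0.05) in each of 13 comparisons, higher to the right and lower to the left of 0, with the count beside each bar. The counts run from 1 for the STA9090 by BGT226 interaction to 6836 between the combinations.

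Several lists did not pass in any comparison with untreated cells. Among 38 genes of the drug targets, the PI3K pathway and tumour genes, 13 rose and 7 fell with STA9090+BGT226 (14 and 7 adjusted over the list alone, median 0.09, camera adjusted p = 0.207). For this list camera's adjusted p was 0.61 with STA9090, 0.792 with PIK75, 0.714 with BGT226 and 0.174 with STA9090+PIK75. BCL2-family genes went 3 up and 3 down of 14 with STA9090+BGT226 (camera adjusted p = 0.884). Interferon-stimulated genes rose in 3 and fell in 3 of 15 with STA9090+PIK75, OAS3 at 0.52 and IFIT1 at -0.75 (camera adjusted p = 0.869). NF-kappa-B genes rose in 1 and fell in 2 of 6, with NFKB2 at 0.90 (camera adjusted p = 0.717). Matrix and EMT genes fell in 7 of 14 with STA9090+PIK75 (camera adjusted p = 0.103), and mitochondrially encoded mRNAs rose in 1 of 13 (camera adjusted p = 0.398).

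Of 18 genes fixed for their link to the drugs or the tumour, the number that passed against untreated cells was 3 with STA9090, 8 with PIK75, 10 with BGT226, 12 with STA9090+PIK75 and 13 with STA9090+BGT226. MYC rose with PIK75 (0.44 ± 0.0942, SE) and BGT226 (0.53 ± 0.0940) and did not pass with STA9090+PIK75 (-0.17, adjusted p = 0.165). MTOR fell with BGT226 (-0.27) and STA9090+BGT226 (-0.28) and rose with PIK75 (0.27), a call that ended without a filter on low counts (0.25), in the fit of the compared groups alone (0.27) and without untreated replicate 1 (0.24). The proliferation marker MKI67 fell with STA9090+PIK75 (-0.42) and STA9090+BGT226 (-0.41). AKT1 fell with STA9090+PIK75 (-0.36) and STA9090+BGT226 (-0.42), and with BGT226 (-0.29), a call that ended without untreated replicate 2 (-0.22), without BGT226 replicate 1 (-0.27) and without BGT226 replicate 3 (-0.29). CTNNB1, which encodes beta-catenin, fell with STA9090+PIK75 (-0.33). PIK3CA, the target subunit of PIK75, did not pass with STA9090 (0.35, adjusted p = 0.135), PIK75 (-0.30, 0.12) or BGT226 (0.25, 0.156). It rose with STA9090+BGT226 (0.40), a call that ended with DESeq2 (0.38) and without untreated replicate 2 (0.31), without STA9090+BGT226 replicate 2 (0.35) and without STA9090+BGT226 replicate 3 (0.32). IGF1R passed with none of the single agents (-0.12, 0.14 and 0.10) and fell with STA9090+PIK75 (-0.25), a call that ended without untreated replicate 1 (-0.22) and without STA9090+PIK75 replicate 1 (-0.20).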

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

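The interaction terms and the fits without single libraries were planned. All other tests in this part, the splits of the libraries included, were chosen after the results they weigh were seen. So was the use of the fits without single libraries to weigh an explanation. No test of single outlying libraries was made, within the groups of 3 or against the spread shared by all groups.

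A test of the difference between groups called attention to these results, given for the genes the report names. The effect of STA9090 differed with and without PIK75 in 1463 genes, and with and without BGT226 in 1 gene. With PIK75 the terms were 1.47 for EGR1, 1.3 for SPRY4 and 1.22 for FOSB, and -2.47 for COL1A1, -2.04 for FAM166B, -1.51 for MUCL1 and -1.47 for DMD, each on the log2 scale. With BGT226 the term of CLSTN3 was 0.76.

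Chance spread of the untreated and STA9090 libraries, which both terms share, would leave few calls in a comparison that uses neither group. The step from PIK75 to STA9090+PIK75 minus the step from BGT226 to STA9090+BGT226 is such a comparison and gave 1539 genes, 580 higher and 959 lower with PIK75, of which 858 were called in the same direction by the interaction with PIK75. Both comparisons use the same STA9090+PIK75 and PIK75 libraries with the same signs, so part of that overlap is built in. If a few genes took counts from the others, the share of unscaled counts left by the 50 most counted genes would change. By the same term it changed by 0.0354 on the log2 scale (SE 0.0788), and the smallest called value was 0.274. TMM scaling already removes a shift common to all genes, so this share does not weigh the scaled calls. Without any 1 of its 12 libraries the interaction called at least 981 genes (without STA9090+PIK75 replicate 1). The tables thus argue against chance spread of the shared libraries and against 1 library carrying the calls. As a hypothesis, inhibition of HSP90 may change how cells answer PIK75 more than how they answer BGT226. The unstated doses within each combination stay open as an untested explanation.

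Other splits of the libraries were counted for each comparison. For the interaction with PIK75, fitted on its own 12 libraries, 1 of 100 drawn splits, the real one, gave as many genes (809, highest other 759). For the interaction with BGT226, 4 of 100, the real one included, gave at least the real 1 gene. The highest other gave 1831, far over the real count, which points to a structure of the samples. The treatments that these splits mix may be that structure, but what gave the calls was not identified. The split with 1831 placed 5 of the 6 libraries with BGT226 on the same side of the term, but of the 9 drawn splits with 5 or 6 there it alone gave calls, and 2 with 3 or 4 there gave calls too. These drawn splits mix treated and untreated libraries within a group, and 89 of the others with PIK75 and 96 with BGT226 gave 0 genes. They therefore do not weigh chance in either interaction. For pairs of groups there are only 10 splits, too few for a share under 0.05, and the real split was the 1 with the most genes in each. Its count and the highest other were 448 and 320 for STA9090, 2947 and 0 for PIK75, 4513 and 0 for BGT226, 6056 and 0 for STA9090+PIK75 and 6287 and 0 for STA9090+BGT226, each against untreated. They were 5914 and 23 for STA9090+PIK75 against STA9090, 3993 and 2 against PIK75, 6378 and 0 for STA9090+BGT226 against STA9090, 424 and 0 against BGT226, 5045 and 1 for PIK75 against BGT226, and 6836 and 0 between the combinations. The split with 320 genes put STA9090 replicate 1 with untreated replicates 1 and 3.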

How the results depend on the processing

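Every alternative in this part was planned, and none was chosen after the results were seen. RLE size factors, the stricter filter and leaving out the 50 most counted genes kept every count of calls within 1.5 times, and RLE kept every count of lists called there too. Where a count moved further the cause was not tested. By construction, a fit of fewer groups estimates the spread from fewer libraries and from those groups alone. In that fit the counts fell with STA9090 and rose with STA9090+BGT226 against BGT226, as given below. A smaller number of libraries alone does not account for both moves.

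Without a filter on low counts, edgeR called 369 genes higher and 400 lower with STA9090, 348 and 479 with STA9090+BGT226 against BGT226, and 82 and 187 for the STA9090 by BGT226 interaction. In that setting STA9090 and PIK75 shared 76 higher genes, and STA9090 and BGT226 102 higher and 63 lower ones. With the compared groups alone in the fit the counts were 0 and 4 with STA9090, 1066 lower with PIK75, 526 and 808 with STA9090+BGT226 against BGT226, and 294 and 515 for the STA9090 by PIK75 interaction. Genes shared by STA9090 and PIK75 were then 0 higher and 2 lower, and by STA9090 and BGT226 0 and 0. Behind the 0 higher genes with STA9090, the fit of all libraries had 2902 genes at an unadjusted p under 0.05 and DESeq2 called 233 higher. Both take the spread over all 6 groups, so they do not weigh the fit of the 2 groups. The highest chi-square of counts per degree of freedom between libraries of a group was 50.32 for untreated and 39.89 for STA9090. It was 30.88 for STA9090+PIK75, 26.58 for PIK75, 16.74 for BGT226 and 11.53 for STA9090+BGT226. That value also depends on depth, and unequal spread was not tested. DESeq2 called 441 lower with STA9090+BGT226 against BGT226, 19 higher and 27 lower for the STA9090 by BGT226 interaction, and 73 genes lower with both STA9090 and BGT226.

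Leaving out 1 library at a time gave 32 to 211 genes higher and 76 to 277 lower with STA9090, 853 to 1257 higher with PIK75, 35 to 107 higher and 99 to 157 lower with STA9090+BGT226 against BGT226, and 344 to 571 higher for the STA9090 by PIK75 interaction. For the STA9090 by BGT226 interaction it gave 0 to 3 higher and 0 to 3 lower. Shared genes were 13 to 19 higher and 25 to 42 lower for STA9090 and PIK75, 14 to 29 and 15 to 26 for STA9090 and BGT226, and 234 to 335 higher for PIK75 and BGT226. Camera called 5 to 9 lists with STA9090 and 7 to 11 for the STA9090 by PIK75 interaction.

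With an estimated correlation camera called 0 lists with STA9090, 5 with PIK75, 4 with STA9090+PIK75, 9 with STA9090+BGT226, 5 with STA9090+PIK75 against STA9090, 5 against PIK75, 2 with STA9090+BGT226 against BGT226, 3 and 1 for the interactions with PIK75 and BGT226, and 6 for PIK75 against BGT226. Fry, which asks whether a list's members change rather than whether they change more than other genes, called 18 lists with STA9090+PIK75, 14 with STA9090+PIK75 against STA9090, 21 and 10 with STA9090+BGT226 against STA9090 and against BGT226, 11 and 5 for the interactions with PIK75 and BGT226, and 19 between the combinations. Of 110 list results named, 75 kept their side of the threshold with an estimated correlation and 35 lost the call, while with fry 103 kept it, 6 gained a call and 1 lost it. None of the 110 reversed.

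Of 293 gene values named, 0 reversed in any setting and 16 lost the call in at least 1. In the fit of the compared groups alone 9 with STA9090 lost it, and MTOR with PIK75 (0.273), which also lost it without a filter on low counts (0.254). PIK3CA with STA9090+BGT226 lost it with DESeq2 (0.376). When 1 library was left out, 8 lost it, HSPA5, MTOR and PIK3CA among them. The named values are a selected part of those the rule takes. Of all 1117 called values it takes, 179 lost the call in at least 1 setting and 0 reversed. With STA9090 35 of its 38 lost it. Without the 50 most counted genes 10 of the named values had no test, because the gene was among the 50.

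With the replicate number as a block the counts were 150 higher and 218 lower with STA9090, 1267 and 1534 with PIK75, 1971 and 2437 with BGT226, 125 and 229 with STA9090+BGT226 against BGT226, and 508 and 814 for the STA9090 by PIK75 interaction, with none of the counts of calls moved by over 1.5 times. Same-numbered libraries showed little shared deviation, and the labels do not say whether a number marks a shared day or culture. Of 45 same-numbered pairs 2 had deviations from the group means that correlated above 0.1 (range -0.172 to 0.15), and 2 of 18 libraries correlated best with their own number.

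In the simulated data, at this depth and with 3 libraries per group, 56% of genes changed 1.5-fold by STA9090 were recovered and 86% of those changed 2-fold. For the STA9090 by PIK75 interaction the shares were 14% and 66%. The sets of 50 changed genes were small beside the 1463 genes that interaction called, so the adjusted threshold was stricter in the simulation. The called log2 values had a median size of 0.598 and a smallest of 0.274. The simulated shares therefore do not give the share of changes missed in the data.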

Other observations

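All tests in this part, and its gene lists except the interferon list, were chosen after their values were seen. The lists so chosen include genes whose changes prompted them. The genes named were also chosen after their values were seen, except HLA-B and COL7A1, which the naming rule takes.

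Genes driven by the circadian clock fell with STA9090 and with STA9090+PIK75. Of 11 measured clock output genes 10 fell with STA9090+PIK75 (10 adjusted over the list alone, median log2 fold change -0.63, camera adjusted p = 1.18e-12, 3.71e-05 with an estimated correlation), NR1D1 (-1.91) and DBP (-1.39) among them. With STA9090 6 fell (10 over the list alone, median -0.57, adjusted p = 1.5e-05 with an estimated correlation), with PIK75 5 fell (0.0131) and with STA9090+BGT226 7 fell (0.0156), whereas with BGT226 1 rose and 1 fell (0.811). Of 3 activators of the clock 1 rose with STA9090. A shift of the clock by HSP90 inhibition may account for falls where STA9090 was given, but not for those with PIK75 alone, and was not tested. The time of day at harvest is not given in the sources used here and stays open as an untested explanation.

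Most genes of a list of basement membrane and collagen genes fell with STA9090+PIK75. Of 11 measured, 10 fell and 1 rose (10 and 1 over the list alone, median log2 fold change -1.46, camera adjusted p = 1.5e-20, 0.000133 with an estimated correlation), with COL4A2 at -2.02 and HSPG2 at -1.62. The member that rose was NID1 (0.83), and COL7A1, a collagen gene outside the list, rose too (1.62). With PIK75 alone 7 fell (median -0.46, 0.0479 with an estimated correlation) and with STA9090 alone 4 fell (median -0.16, 0.0317), while with BGT226 5 rose (0.696). No technical or biological explanation was tested for this fall.

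Host RNAs of small nucleolar RNAs rose with BGT226, 12 of 27 (14 over the list alone, median log2 fold change 0.52, camera adjusted p = 9.16e-16, 0.0118 with an estimated correlation). If reads of the small RNAs were counted in their hosts, those RNAs would rise at least as much. The 22 measured inside the hosts had a median of 0.268. With STA9090 their median was 0.287, while that of the hosts was -0.0348. But 14 of the 22 were below 2 CPM, and only 3 of the 12 hosts that rose with BGT226 held 1 at 2 CPM or above. Counted small RNAs therefore stay open. Such hosts are degraded during translation, and decay factors under feedback from that pathway rose as a list (3 of 9, median 0.28, camera adjusted p = 0.0213, 0.0483 with an estimated correlation). With STA9090+BGT226 15 of the 27 hosts rose and 2 fell (median 0.471, 0.0156 with an estimated correlation), and of the decay factors 5 rose and 0 fell (median 0.379, 0.0264). With STA9090+PIK75 15 of the 27 hosts rose (median 0.488, 0.1 with an estimated correlation), while of the decay factors 2 rose and 1 fell (0.345). Less nonsense-mediated decay therefore stays open for BGT226, as does more transcription of the hosts, which was not tested.

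HLA class I genes fell with STA9090, HLA-B by 1.12. In a list of class I presentation 4 of 13 genes fell (5 over the list alone, camera adjusted p = 1.29e-08, 0.00374 with an estimated correlation). Genes of presentation other than HLA genes did not pass by edgeR's test for B2M (-0.16, adjusted p = 0.333), TAP1 (-0.06, 0.869), NLRC5 (-0.29, 0.387) and ERAP1 (0.16, 0.57). Reads moved between near copies would leave their sum in place, but the summed count of 10 class I genes and pseudogenes fell (log2 fold change -0.694, SE 0.0782, adjusted p = 0.000319, from 172 ± 12.2 to 107 ± 4.73 CPM, SD, n = 3). No single library carried the fall of the sum, which stayed at -0.635 or below without each of the 6 libraries in turn, the highest without untreated replicate 2. Less interferon signalling would lower the interferon list. Its median was 0.109, but its 15 members went both ways (5 below 0, SD 0.284) and only 3 lay at 10 CPM or above, so that explanation stays open.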
